A study of Mus musculus with 6 samples.

How the data were processed

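Gene expression was measured in primary hepatocytes of 6 adult C57BL/6 mice, 3 with a doxycycline-inducible miR-143 transgene and 3 wildtype littermates, with 1 Affymetrix array per animal. Per the labels' protocols, hepatocytes were snap-frozen after collagenase perfusion, total RNA was extracted with Trizol, and biotinylated cDNA was made with the whole transcript sense target protocol. The deposited values are on a log scale, taken here as log2 because they ran from 1.60 to 15.2 over the 6 arrays, the span of a scanner's intensities. Partek is named, without a version, per the submitters' processing notes. How the authors corrected the background, normalized and summarized the log2 values is not given in the sources used here.

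The deposited table held 234873 probe sets. In the platform annotation, whose symbols are those of its own date, 212097 probe sets had 1 gene symbol, 4475 had several and 18301 had none, and only the first kind was used for genes. The gene lists, the rule for named genes, the main tests and the rules of processing below were set before the data were examined. The rule for scaling was to use the deposited values if the 5th to 95th percentiles of the arrays differed by at most 0.1, and otherwise to quantile normalize them. The 75th and 95th percentiles differed by up to 0.127 and 0.135, so the log2 values were quantile normalized. A gene's value was the mean of its probe sets (median 8 per gene, from 1 to 320; 2292 genes with 1), which gave 20416 genes. Genes whose mean over the 6 arrays lay in the lowest 25% (under log2 5.06) were left out, 5104 in all, which left 15312. No detection call was used, so a low value cannot be told from background. The number of arrays limits the precision. The median residual SD of a gene, as moderated by limma over all genes, was 0.183.

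Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group only, two-sided) with Benjamini-Hochberg adjustment over all genes tested, and differences are miR-143DOX minus control. Adjusted p-values of genes come from this fit, also where they are adjusted over the list alone. The latter adjustment is not corrected across lists, so some lists would hold such a gene with no effect. Here only the fatty acid oxidation, acute phase and female-biased lists held one. How many of the 37 would with no effect was not tested. A total of 37 gene lists (pathways, and markers of hepatocytes and of other cells a liver preparation could hold) were written in advance, with 892 genes. Of these, 813 were found under the written symbol, 13 under an older or newer symbol that belonged to that gene alone, and 66 were not used. Lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01 and adjusted over the 37 lists, and again with camera with an estimated correlation and with fry. Camera compares a list with the other genes; fry asks whether its genes move, on balance, one way. The median, mean and test differed in sign for 7 lists, of which none passed: insulin and AKT signalling, circadian clock, interferon-stimulated genes, urea cycle, periportal hepatocyte genes, cholangiocyte and neutrophil. Array scores of lists were compared by exact permutation of the 6 arrays. Intervals are 95% intervals of the fit.

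Genes named in the text followed a rule fixed in advance. As fewer than 10 genes passed 5% FDR, it took the 10 genes with the smallest unadjusted p in each direction, skipping predicted genes, up to 4 members of each list with the smallest unadjusted p, and a fixed set for the miR-143 and insulin question and for the animals' sex. Alternatives were the deposited values as they are, arrays centred on medians, other filters on dim genes, the median or the brightest probe set of a gene, an intensity trend with a robust prior, array weights, the replicate number as a block, and each array left out. The brightest probe set, by its mean over the arrays, stands for a gene by 1 probe set and leaves out its others. A covariate for the clock genes (Dbp minus Arntl, as a straight line), and the arrays at its extremes left out together, were added after seeing the data. The steps were tested on 10 simulated data sets with 200 changed genes among 15312 each. They recovered 78.3% of 2-fold changes (70 to 85% per set) with a mean fitted difference of 0.99, 97.6% of 4-fold changes, and a list shifted by 0.3 in 10 of 10 sets with the preset correlation and 8 of 10 with an estimated one. Noise was drawn independently for each gene, so the simulated lists held no correlation between genes. The real lists had estimated correlations of up to 0.739, and the list result does not carry over to correlated members. The planned test of genes with miR-143 seed matches in their 3' untranslated regions was not run, since untranslated sequences were not used here.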

Results

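Hepatocytes were isolated by liver perfusion from adult C57BL/6 mice that carried a doxycycline-inducible miR-143 transgene (miR-143DOX) and from wildtype littermates (control). All animals drank water with doxycycline at 4 mg/ml and 10% sucrose for 8 days, so the control mice received the drug without the transgene. miR-143 is a microRNA, a short RNA that lowers the level or translation of transcripts it pairs with, and the comparison asks which hepatocyte transcripts differ when it is induced. RNA of 3 mice per group was read on Affymetrix arrays, 1 array per mouse, and 15312 genes were tested. The 6 arrays correlated with each other at Pearson r of 0.936 to 0.954 across probe sets, and their median log2 intensities lay within 0.0665 of each other. All 6 arrays had the pattern of male animals. Xist, the transcript of the silenced X chromosome, stood at 3.94 ± 0.09 in miR-143DOX against 3.99 ± 0.04 in control (log2, SD, n = 3 each), near the floor, while the Y-linked gene Eif2s3y stood at 8.81 ± 0.14 in miR-143DOX against 8.62 ± 0.31 in control. The Y-linked genes Uty and Kdm5d stood at 7.89 ± 0.11 in miR-143DOX against 7.87 ± 0.33 in control and at 6.80 ± 0.28 in miR-143DOX against 7.36 ± 0.28 in control. The groups were separate for Kdm5d, at a difference of -0.56 (95% interval -0.95 to -0.16), which did not pass the test over all genes and was 0.088 with its brightest probe set. The level of miR-143 itself was not analysed here.

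Transcripts of fatty acid oxidation and PPARalpha target genes were higher as a group in miR-143DOX hepatocytes, and those of the unfolded protein response and of the acute phase were lower as groups, in camera with a preset correlation. These calls were lost with an estimated correlation, at adjusted p = 0.72, 0.72 and 0.455, and the array scores of the first pair of lists overlapped between the groups (exact two-sided permutation p = 0.2 each). For the acute phase list the estimate was 0.0144, near the preset 0.01, so its size alone does not account for that loss. With an estimated correlation camera also uses the 4 residual degrees of freedom of the fit. With a preset one it uses far more, set by the number of genes. A call lost between the 2 forms is therefore not a measure of correlation between genes alone. PPARalpha is the receptor that switches on fatty acid oxidation in the fasted liver. Of 33 genes on its list, 29 lay above 0, with a median difference of 0.21 (log2, miR-143DOX minus control), and of 30 genes of the unfolded protein response 27 lay below 0, with a median of -0.19. Of 36 acute phase and inflammation genes 27 lay below 0, with a median of -0.16. No single gene passed 5% false discovery rate (FDR) over all genes in limma's moderated test, with 469 at an unadjusted p under 0.05. Of 37 gene lists, 12 passed camera with a preset correlation, 7 higher and 5 lower, and 0 passed camera with an estimated correlation or fry (2 and 1 at an unadjusted p under 0.05). Without miR-143DOX replicate 1 the lists past preset camera numbered 6.

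In the fatty acid oxidation list, Vnn1, the pantetheinase vanin-1, measured 9.25 ± 0.38 in miR-143DOX against 8.14 ± 0.12 in control (log2, SD, n = 3 each), which is 2.15-fold. Cyp4a14, a fatty acid omega-hydroxylase, measured 10.43 ± 0.56 in miR-143DOX against 9.29 ± 0.56 in control (2.21-fold), and Acaa1b, a peroxisomal thiolase, 9.82 ± 0.05 in miR-143DOX against 9.28 ± 0.18 in control (1.45-fold). These 3 genes rose at 5% FDR adjusted over the list alone, with limma adjusted p of 0.00201, 0.0259 and 0.0259, against 0 of 33 over all genes tested (6 at an unadjusted p under 0.05). Over the list alone, 1 gene passed without control replicate 3, miR-143DOX replicate 1 or miR-143DOX replicate 2, 2 without control replicate 2, 4 without miR-143DOX replicate 3, 8 without control replicate 1 and 9 with array weights. The fatty acid transporter Cd36 differed by 1.03 with a standard error of 0.33 and missed that threshold (adjusted p = 0.0776 over the list alone). Cd36 was 0.63 without miR-143DOX replicate 1 and 0.42 without both arrays at the clock extremes. Vnn1 passed over the list alone with each array left out, while Acaa1b and Cyp4a14 did not pass, at adjusted p of 0.136 and 0.198, without miR-143DOX replicate 2. Both also missed the threshold without control replicate 2 (0.121 and 0.112), control replicate 3 (0.059 and 0.0773) and miR-143DOX replicate 1 (0.0881 and 0.0901), and so did Acaa1b without miR-143DOX replicate 3 (0.052). Acaa1b missed it as well with the median over its probe sets (0.323, at a difference of 0.33) and with the brightest probe set (0.182), and Cyp4a14 with an intensity trend and robust prior (0.16). Vnn1 and Acaa1b were higher in every miR-143DOX mouse than in every control mouse, while Cyp4a14 and Cd36 overlapped between the groups. The list passed camera with its preset correlation (adjusted p = 3.89e-09), but adjusted p = 0.72 with an estimated correlation. Its median was 0.11 without miR-143DOX replicate 1 and 0.31 without control replicate 1. Markers of hepatocytes as a class had a median of -0.02 (preset adjusted p = 0.11).

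The unfolded protein response list includes genes of chaperones and folding enzymes of the endoplasmic reticulum. It also holds other genes, such as Trib3, which differed by 0.34 (standard error 0.18). Of its 30 genes, 5 lay lower at an unadjusted p under 0.05 and 0 higher. The differences were -0.59 for Creld2 (standard error 0.19), -0.53 for the co-chaperone Dnajb11 (0.18), -0.46 for Manf (0.16) and -0.53 for the chaperone Hyou1 (0.19). Creld2, Dnajb11 and Manf did not overlap between the groups. Without control replicate 3, Creld2 stood at -0.38, Dnajb11 at -0.32 and Hyou1 at -0.31, and with the median over its probe sets Manf stood at -0.75. No member passed 5% FDR over all genes or adjusted over the list alone, where the lowest adjusted p was 0.136. The list fell in camera with its preset correlation (adjusted p = 3.57e-07), with adjusted p = 0.72 with an estimated correlation. Without control replicate 3, the array with the highest values of this list, the median was -0.09, and with the brightest probe set of each gene it was -0.09. Sinusoidal endothelium markers had a median of -0.12 (adjusted p = 0.73 with an estimated correlation), and of -0.027 without miR-143DOX replicate 2, where their preset call was lost.

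The acute phase list holds plasma proteins that the liver secretes in inflammation, with receptors and feedback genes of cytokine signalling. Serum amyloid gene Saa2 measured 7.11 ± 0.12 in miR-143DOX against 7.79 ± 0.37 in control (log2, SD, n = 3 each) and fell at 5% FDR adjusted over the list alone (limma adjusted p = 0.0475). Socs3, a feedback inhibitor of cytokine receptors, went the other way, at 7.54 ± 0.05 in miR-143DOX against 6.98 ± 0.16 in control, and rose by the same criterion (adjusted p = 0.0475). These 2 of 36 genes passed over the list alone, and 0 over all genes (1 higher and 6 lower at an unadjusted p under 0.05). Over the list alone, 7 passed without miR-143DOX replicate 1, 4 with the replicate block, 2 without control replicate 1, 1 without control replicate 2 or miR-143DOX replicate 3, and 0 without control replicate 3 or miR-143DOX replicate 2. Adjusted p of Saa2 and Socs3 was 0.175 and 0.175 without control replicate 3, 0.14 and 0.14 without miR-143DOX replicate 2, and 0.0697 and 0.0697 without miR-143DOX replicate 3. It was 0.108 for Saa2 without control replicate 1 and 0.0887 for Socs3 without control replicate 2. On the deposited values without further normalization 0 members passed (0.0556 for both), and 0 with the brightest probe set (0.209 and 0.608, with Socs3 at 0.30). Saa2 also missed the threshold with the median over probe sets (0.0678), array weights (0.0789), the clock covariate (0.0633) and both arrays at the clock extremes left out (0.071). The interleukin receptor genes Il1r1 and Il6ra differed by -0.73 and -0.46, with standard errors of 0.22 and 0.15, and did not pass (adjusted p = 0.083 and 0.0873 over the list alone). All 4 genes were separate between the groups. The mean deviation of the list was -0.09 ± 0.04 in miR-143DOX and 0.09 ± 0.05 in control arrays (SD, n = 3 each, exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give). Preset camera gave adjusted p = 5.94e-05, and the test gave adjusted p = 0.455 with an estimated correlation. The median lay between -0.16, without control replicate 2, and -0.11, without miR-143DOX replicate 1, with each array left out in turn. Kupffer cell markers, for the resident macrophages that make inflammatory cytokines, had a median of 0.06 (preset adjusted p = 0.592), and sinusoidal endothelium markers a median of -0.12.

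**Figure D1:**
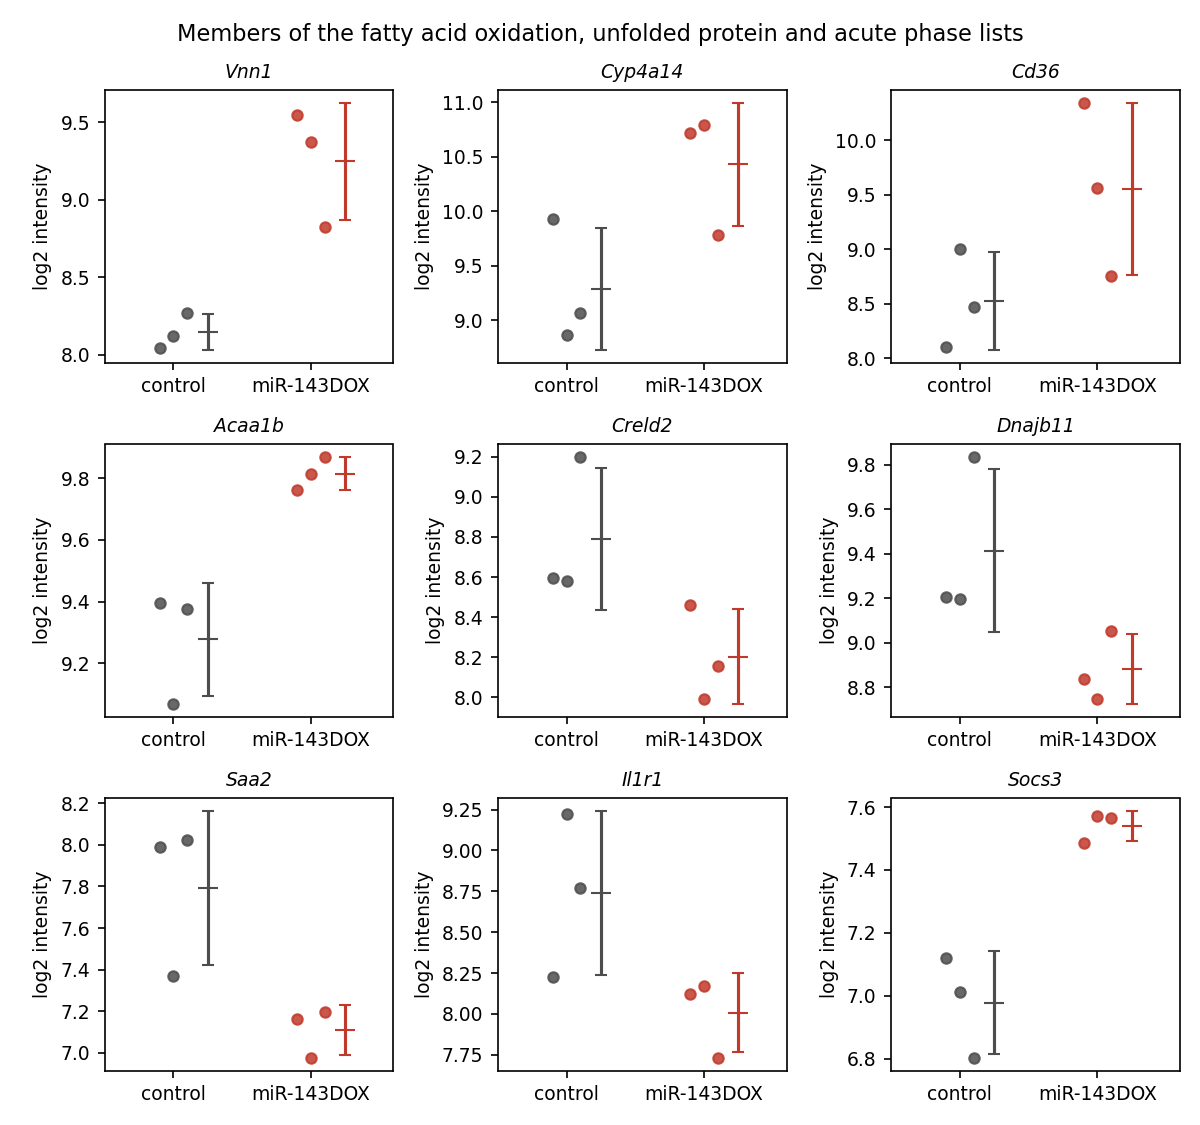
Log2 intensity of 9 genes on each array, with points for the 3 mice of a group beside the group's mean and SD; each panel has its own scale. Vnn1, Acaa1b and Socs3 were higher, and Creld2, Dnajb11, Saa2 and Il1r1 lower, in all miR-143DOX mice than in all control mice, while Cyp4a14 and Cd36 overlapped.

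Another 9 of the 37 lists passed preset camera at 5% FDR. Genes expressed more in male than in female mouse liver fell as a list (median -0.23, preset adjusted p = 3.41e-04, adjusted p = 0.72 with an estimated correlation), with differences of -1.06 for Selenbp2 (standard error 0.33) and -0.82 for the oxysterol hydroxylase Cyp7b1 (0.35). Selenbp2 was -0.66 without both arrays at the clock extremes, and Cyp7b1 was -0.41 without miR-143DOX replicate 1 and -1.33 without miR-143DOX replicate 3. Sinusoidal endothelium markers fell too (median -0.12, preset adjusted p = 0.00177, adjusted p = 0.73 with an estimated correlation), with -0.37 for Clec4g, as did pericentral hepatocyte genes (median -0.06, preset 0.0291, adjusted p = 0.72 with an estimated correlation), with -0.49 for Cyp1a2 and -0.41 for Lect2 (-0.17 with its brightest probe set and -0.21 with the median over its probe sets). Targets of the oxidative stress factor NRF2 rose (median 0.13, preset adjusted p = 0.0026, adjusted p = 0.72 with an estimated correlation), with 0.47 for the glutathione synthesis gene Gclc and 0.65 for Me1. These were 0.27 and 0.35 without control replicate 1, and Me1 was 0.41 without miR-143DOX replicate 1. Without both arrays at the clock extremes Gclc was 0.15 and Me1 0.10. Immediate early and isolation stress genes rose as a list (median 0.14, preset 0.00283, adjusted p = 0.72 with an estimated correlation). Their members Gadd45g, Gadd45a and Atf3 differed by 0.92, 0.62 and 0.55, and the heat shock gene Hspa1a by -0.92. Without control replicate 3, Atf3 stood at 0.26 and Hspa1a at -0.60, and without control replicate 1 Gadd45g stood at 0.52. Lipogenesis genes (median 0.17, preset 0.0465, adjusted p = 0.73 with an estimated correlation) included the fatty acid synthase gene Fasn at 0.51 and Acly at 0.55. Acly was 0.22 and Fasn 0.31 without miR-143DOX replicate 1, Acly was 0.32 without control replicate 1 and 0.83 without control replicate 2, and it turned to -0.011 without both arrays at the clock extremes. The other lists to pass were the 8 B cell markers (median 0.17, preset 0.0047, adjusted p = 0.72 with an estimated correlation), with 0.34 for Faim3 (-0.053 with the median over its probe sets), and oxidative phosphorylation (median 0.07, preset 0.0184, adjusted p = 0.842 with an estimated correlation), with 0.31 for Uqcrb (0.19 with array weights). Cell cycle genes passed closest to the threshold (median 0.08, preset 0.0471, adjusted p = 0.72 with an estimated correlation), with 0.38 for Ccnb2 (0.11 with its brightest probe set). Only 8 of 16 written B cell markers were tested, and they were dim, at a median level percentile of 11.1 among tested genes. Cell cycle genes stood at 26.6 by that measure. Values this low cannot be told from background here. In these 9 lists, 0 members passed 5% FDR adjusted over the list alone or over all genes. Members at an unadjusted p under 0.05 numbered 2, 1, 2, 2, 5, 2, 1, 0 and 1, in the order the lists are given here.

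Each of these 9 calls was lost without some array. Without control replicate 1, the calls lost were those with medians of 0.12 for NRF2 targets, 0.12 for B cell markers, -0.00853 for pericentral genes, 0.031 for lipogenesis and 0.11 for cell cycle genes. Past the test, but moved by over 1.5 times, were medians of 0.19 for oxidative phosphorylation. Without control replicate 2, the call lost had a median of -0.056 for pericentral genes. Without control replicate 3, the calls lost were those with medians of -0.11 for endothelial markers, 0.054 for immediate early genes, -0.027 for oxidative phosphorylation and 0.060 for cell cycle genes. Past the test, but moved by over 1.5 times, were medians of -0.13 for male-biased genes and -0.14 for pericentral genes. Without miR-143DOX replicate 1, the calls lost were those with medians of -0.064 for male-biased genes, 0.073 for NRF2 targets, 0.13 for B cell markers, -0.00404 for oxidative phosphorylation, -0.00746 for pericentral genes, 0.054 for lipogenesis and 0.023 for cell cycle genes. Past the test, but moved by over 1.5 times, were medians of -0.25 for endothelial markers. Without miR-143DOX replicate 2, the call lost had a median of -0.027 for endothelial markers. Past the test, but moved by over 1.5 times, were medians of -0.19 for pericentral genes. Without miR-143DOX replicate 3, the calls lost were those with medians of 0.13 for immediate early genes, -0.023 for pericentral genes and 0.14 for cell cycle genes. Past the test, but moved by over 1.5 times, were medians of -0.36 for male-biased genes, 0.26 for B cell markers and 0.15 for oxidative phosphorylation. Oxidative phosphorylation turned its sign without control replicate 3 and without miR-143DOX replicate 1. The lists of fatty acid oxidation, unfolded protein response and acute phase passed preset camera with each of the 6 arrays left out.

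Over 17 other settings of the expression values, single arrays left out included, lipogenesis and the cell cycle each passed in 6, pericentral genes in 7, oxidative phosphorylation in 13, NRF2 targets in 14, and male-biased genes, immediate early genes and sinusoidal endothelium markers in 15 each. B cell markers passed in 11 of 16. With the brightest probe set of a gene the median of male-biased genes was -0.043 and that of pericentral genes turned to 0.060, and neither passed; nor did lipogenesis, the cell cycle, B cell markers or oxidative phosphorylation. Lipogenesis was also lost on the deposited values (0.15), with arrays centred on their medians (0.15), without a filter on dim genes (0.17), with the median over probe sets (0.18), with array weights (0.13) and with the clock covariate (0.097). Without both arrays at the clock extremes, the medians were 0.032 for NRF2 targets, -0.065 for lipogenesis, -0.00295 for the cell cycle, -0.00472 for pericentral genes and 0.11 for B cell markers, none of which passed. In that setting male-biased genes (-0.12) and sinusoidal endothelium markers (-0.25) passed. With the replicate block, lipogenesis, the cell cycle and pericentral genes did not pass.

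**Figure D2:**
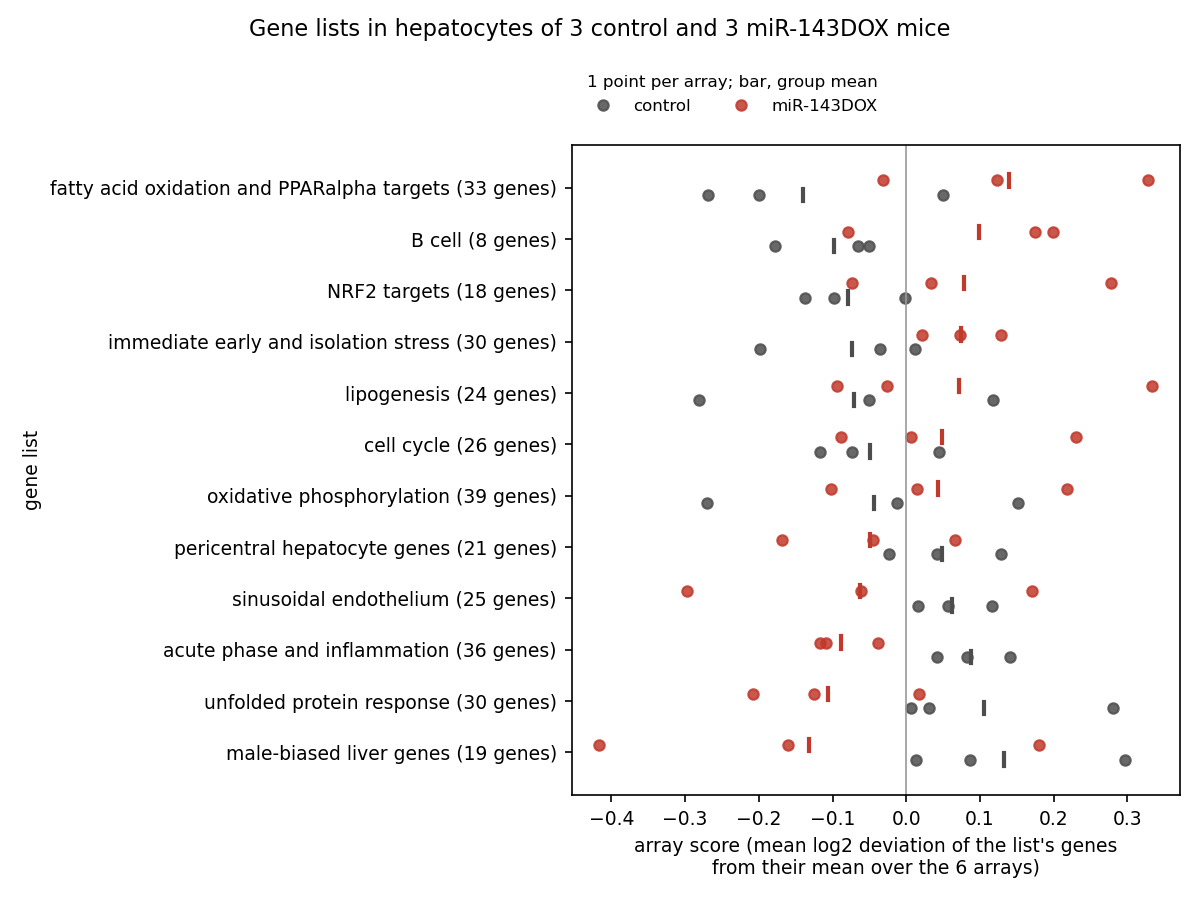
Score of each array, the mean log2 deviation of a list's genes from their mean over the 6 arrays, for the 12 lists past preset camera, with 1 point per mouse and bars at the group means. The groups were separate for the acute phase list and for the immediate early list and overlapped for the other 10.

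Over all 15312 genes, 0 passed 5% FDR in limma (smallest adjusted p = 0.735). Of 234873 single probe sets 0 passed as well, with 10516 at an unadjusted p under 0.05 where 11743.7 would be called with no effect. At an unadjusted p under 0.05 there were 469 genes in the gene test, 212 higher and 257 lower in miR-143DOX, where 765.6 would be called with no effect. Without miR-143DOX replicate 2 there were 300 and without miR-143DOX replicate 3 there were 1128. The groups did not overlap for 7.13% of genes, where chance gives 10%. The 20 named genes of smallest unadjusted p therefore did not pass the threshold and are given as values. On the higher side, beside Vnn1, Cyp4a14 and Socs3, were Ppih, of the cyclophilin family, at 1.12, Tceal3 at 1.04, Igh-3 at 0.96, Amac1 at 0.71, the acyl-CoA thioesterase gene Acot9 at 0.71, BC029722 at 0.67 and Pnmal1 at 0.61. On the lower side, beside Hspa1a, were Klk1b21 at -0.99, the class II antigen loading gene H2-DMb1 at -0.86, Clec2d at -0.75, Ttc39a at -0.61, Zfp161 at -0.60, the poly(A)-binding protein gene Pabpc4 at -0.59, Tmem68 at -0.58, the amino acid transporter Slc43a1 at -0.57 and the mitochondrial ribosomal gene Mrps17 at -0.53. Their standard errors ran from 0.13 for Mrps17 to 0.30 for Cyp4a14. Ppih, Tceal3, BC029722, Klk1b21, H2-DMb1 and Hspa1a rest on 1 probe set each. With the brightest probe set of a gene, Ttc39a turned to 0.021, and Pabpc4 stood at -0.016, Mrps17 at -0.024 and Zfp161 at -0.17. In that setting Amac1 was 0.32, Igh-3 0.56, Acot9 0.43 and Tmem68 -0.38, and with the median over probe sets Pnmal1 was 1.10. With that median Pabpc4 stood at -1.02, Ttc39a at -0.82, Zfp161 at -0.34 and Mrps17 at -0.23. In 10 simulated data sets with the spread of these arrays, the same test found 78.3% of 2-fold and 97.6% of 4-fold changes among 15312 genes. Each set held 200 changed genes and noise independent between genes. With fewer changed genes the adjusted cutoff is stricter, so these rates do not bound the number of 2-fold changes missed here. In the real data the median 95% interval of a gene reached 0.33 to each side.

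A known interest of this mouse model is whether miR-143 acts on insulin signalling through Osbpl8, and the genes of that question were fixed in advance. Osbpl8, an oxysterol-binding protein and reported miR-143 target, measured 8.63 ± 0.35 in miR-143DOX against 8.62 ± 0.40 in control (log2, SD, n = 3 each). Its difference of 0.01 had a 95% interval of -0.47 to 0.49 and took either sign under other settings (-0.19 to 0.27), as did those of Irs1, Irs2, Akt1, Akt2, G6pc and Pck1. The 11 tested genes of the oxysterol-binding family had a median of 0.01 (preset adjusted p = 0.955), and the 23 reported miR-143 targets a median of 0.03 (preset adjusted p = 0.445), with Fosl2 at 0.34 (0.22 without control replicate 3) and Hk2 at 0.18 (-0.36 with its brightest probe set). The insulin receptor gene Insr differed by -0.34 (-0.73 to 0.06), the transcription factor gene Foxo1 by -0.26 (-0.59 to 0.07) and Gsk3a by -0.29 (-0.62 to 0.03). Without miR-143DOX replicate 1, Insr stood at -0.16 and Gsk3a at -0.18, and without miR-143DOX replicate 3 Foxo1 stood at -0.17. The differences were 0.04 for Irs1, 0.16 for Irs2, -0.11 for Akt1 and -0.10 for Akt2, all within intervals that held 0. Among the 36 genes of insulin and AKT signalling 0 passed over all genes or adjusted over the list alone (0 at an unadjusted p under 0.05), and the list's median was 0.0037 (preset adjusted p = 0.541). With an array left out that median ran from -0.049 to 0.0056. The medians of reported miR-143 targets and of the oxysterol-binding family then ran from 0.0098 to 0.075 and from -0.024 to 0.025. The gluconeogenic genes G6pc and Pck1 differed by 0.08 (-0.23 to 0.38) and 0.02 (-0.31 to 0.34), while their coactivator Ppargc1a differed by -0.54 (-1.01 to -0.07) and the serine dehydratase gene Sds by -0.34. Ppargc1a was -0.28 without control replicate 1, its highest array, and -0.18 with its brightest probe set, and Sds was -0.21 without miR-143DOX replicate 3. The kinase gene Mapk7 and the transcription factor gene Klf5, further reported targets, differed by 0.05 (-0.24 to 0.34) and 0.11 (-0.23 to 0.46). With an array left out Mapk7 ran from 0.0095 (without control replicate 3) to 0.13 (without miR-143DOX replicate 3), and Klf5 from 0.026 (without miR-143DOX replicate 2) to 0.24 (without miR-143DOX replicate 3). The intervals bound transcript levels, and protein was not measured.

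**Figure D3:**
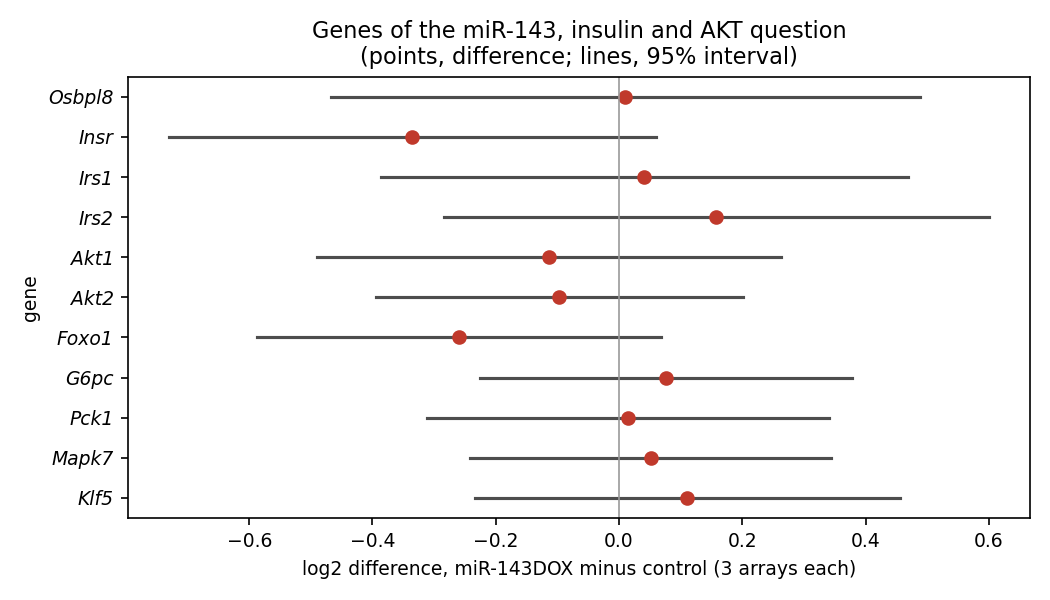
Log2 difference between miR-143DOX and control (3 arrays each) for 11 genes fixed in advance, with points at the difference and lines over the 95% interval. Every interval held 0, from Insr at -0.34 to Irs2 at 0.16.

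Other metabolic lists did not pass preset camera. Glycolysis genes had a median of 0.11 (adjusted p = 0.0896), but the regulatory enzyme genes Pfkfb3 and Pfkfb2 lay at -0.96 and -0.54, with standard errors of 0.25 and 0.17 (adjusted p = 0.0583 and 0.0833 over the list alone). Cholesterol synthesis and uptake genes had a median of -0.10 (adjusted p = 0.0505), with -0.44 for squalene epoxidase, Sqle, -0.34 for Cyp51 and -0.46 for Sc4mol (-0.24 without control replicate 1). Bile acid genes had a median of -0.03 (adjusted p = 0.541), with -0.95 for Cyp7a1, the rate-limiting enzyme of bile acid synthesis, whose SD in miR-143DOX was 1.21. Without miR-143DOX replicate 1 the difference of Cyp7a1 was -0.25. In the list of genes expressed more in female liver (median 0.05, adjusted p = 0.356), Abcd2, a peroxisomal fatty acid transporter, rose by 1.01 at 5% FDR adjusted over the list alone (adjusted p = 0.0334; 1 of 10 genes, 0 over all genes), and Cyp2b9 measured 6.51 ± 1.35 in miR-143DOX against 5.51 ± 0.08 in control, at a difference of 0.34 without miR-143DOX replicate 1 and 1.69 without miR-143DOX replicate 3. Adjusted p of Abcd2 over the list alone was 0.0801 without control replicate 1, 0.0981 without control replicate 3, and 0.111 and 0.165 without miR-143DOX replicates 1 and 2. It was 0.0718 with the brightest probe set, 0.117 with an intensity trend and robust prior, and 0.171, at a difference of 0.58, without both arrays at the clock extremes. The medians, with the preset adjusted p in parentheses, were -0.02 (0.254) for gluconeogenesis, 0.04 (0.445) for glycogen metabolism, -0.01 (0.782) for xenobiotic metabolism, 0.0046 (0.955) for the urea cycle and amino acid catabolism and 0.01 (0.697) for periportal hepatocyte genes. They were -0.10 (0.0569) for antigen presentation, 0.03 (0.867) for interferon-stimulated genes, 0.07 (0.134) for p53 targets and 0.02 (0.813) for the circadian clock. The clock list mixes genes of opposite phase, so its median and 1-way test cannot show a difference in clock state between the groups. Dbp minus Arntl differed by -0.994 (log2, miR-143DOX minus control), with wide ranges within each group, and that difference was not tested.

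Among markers of other cells, those of stellate cells and fibroblasts had a median of 0.04 (0.556), cholangiocytes 0.07 (0.955), T and NK cells 0.06 (0.356), neutrophils 0.03 (0.782), erythroid cells -0.04 (0.782), platelets 0.06 (0.867) and pancreatic acinar cells 0.16 (0.0569), again with the preset adjusted p in parentheses. None of these 7 lists passed. The hepatocyte markers Serpina1a and Asgr2 differed by -0.98 and -0.33, with standard errors of 0.37 and 0.14. Serpina1a was -0.54 without control replicate 3 and -0.59 without miR-143DOX replicate 1, and Asgr2 was -0.22 with its brightest probe set.

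Of the 22 tested genes of the circadian clock list, 16 (72.7%) had an SD within groups above the 90th percentile of all genes, where 10% of all genes lay. Hlf, Cry1, Rora, Cry2, Nr1d1 and Csnk1d did not. Arntl, a core activator of the clock, ranged over 4.71-fold among control mice and 3.71-fold among miR-143DOX mice, and Dbp, an output gene that peaks in the opposite phase, over 4.11-fold and 5.13-fold. Dbp stood at 10.08 in control 1 and 6.99 in miR-143DOX 1, the extremes of the 6 arrays, and Arntl at 5.56 and 8.24. By SD within groups, Dbp ranked 6 and Arntl 10 of 15312 genes. This count, and Arntl, Dbp, Npas2, Per3, Tef and the members named without a wide spread, were chosen after their values were seen.

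**Figure D4:**
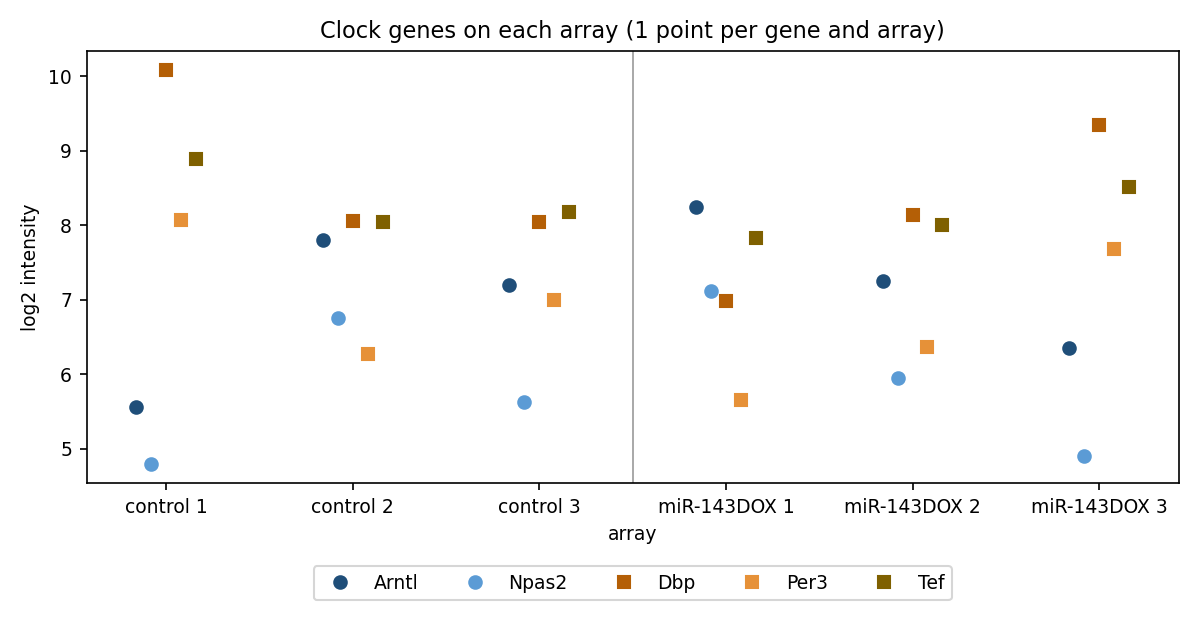
Log2 intensity of 5 clock genes on each of the 6 arrays, with 1 point per gene and array. Dbp ranged from 6.99 in miR-143DOX 1 to 10.08 in control 1, where Arntl had its highest and lowest values.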

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

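The clock covariate and the joint removal of control 1 and miR-143DOX 1 were chosen only after the result was seen. The count of genes past 5% FDR stayed at 0 in the 15 planned settings of the gene test, among them each array left out (0 to 0), and with the clock covariate. It was 1 without both arrays at the clock extremes: Dcpp1, at -1.45 (adjusted p = 0.0414), chosen after its values were seen, against -0.77 with all arrays; fewer samples entered that fit, and the cause was not tested. Genes at an unadjusted p under 0.05 numbered 1021 with array weights, 299 with the dimmest 50% of the genes left out (fewer genes tested) and 300 to 1128 with an array left out, the highest without miR-143DOX replicate 3 and the lowest without miR-143DOX replicate 2. Lists past 5% FDR fell from 12 to 7 with the brightest probe set of a gene, 0 with camera with an estimated correlation and 0 with fry (2 and 1 lists at an unadjusted p under 0.05), and numbered 6 to 13 with an array left out, the lowest without miR-143DOX replicate 1. The cause was not tested.

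The replicate numbers were not taken as pairs, since no label ties a transgenic animal to a given control. Same-numbered arrays correlated at 0.107, 0.0468 and 0.296 after removal of group means, and 4 of 6 arrays correlated best with their own number. A link between same-numbered arrays is therefore not excluded. With the replicate block 734 genes had an unadjusted p under 0.05, 0 passed 5% FDR and 9 lists passed.

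Of the 12 lists past preset camera, fatty acid oxidation, unfolded protein response and acute phase passed in all 17 settings of the expression values. These settings reuse the same arrays and the preset correlation of 0.01, while the estimated correlations of these lists were 0.337, 0.225 and 0.0144. Splits of the arrays that mix the groups also passed 4 to 10 lists each by preset camera. The direction of the test reversed, without passing, for B cell markers with the median over probe sets (median 0.054, test lower). It also reversed, without passing, for lipogenesis without both arrays at the clock extremes (-0.065). The same held for oxidative phosphorylation without control replicate 3 (-0.027, the lowest with an array left out, highest 0.19). Medians of further lists that did not pass changed sign too. They were 0.060 for pericentral genes with the brightest probe set and -0.00404 for oxidative phosphorylation without miR-143DOX replicate 1. Cell cycle genes stood at -0.00295 without both arrays at the clock extremes. The cause of these turns was not tested. B cell markers had fewer than 5 genes, and so no value, with the dimmest 50% left out. Of the values of named genes under other settings, 2745 kept their sign and 85 changed it. All alternatives of the miR-143 site test were not run. Dim genes rest on signal near background, which these values do not separate.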

Other observations

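The tests of the count of genes and of lists over other splits, of the clock genes and of the share of hepatocytes, and the splits of the acute phase list, were chosen only after the result was seen; the splits of the other lists and the single-array test were chosen before.

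The first principal component held 34.2% of the variance, of which 11.5% lay between groups, and set control 1, miR-143DOX 1 and miR-143DOX 2 (scores 9.67, 18.6 and 11.4) apart from control 2, control 3 and miR-143DOX 3 (-3.11, -21.3 and -15.3). The largest positive mean loadings were those of genes expressed more in female liver and of fatty acid oxidation (12.1 and 11.7, in thousandths), and the most negative those of genes expressed more in male liver and of the unfolded protein response (-14.1 and -8.43). The component most aligned with the groups was the fourth, with 12.6% of the variance, of which 51.2% lay between groups.

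The 6 arrays allow 10 splits into 3 and 3, which is too few for a share under 0.05. For genes past 5% FDR the real split gave 0, which any split reaches, so that 10 of 10 carries no information on chance; the highest other gave 3. At an unadjusted p under 0.05, 8 of 10 splits gave at least the real 469 genes, and the highest other gave 2234, which points to a structure of the samples: it is the split along the first principal component. For lists past preset camera the real split gave 12, reached by 1 of 10, and the other splits gave 4 to 10. That test thus passed lists under every split.

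The fatty acid oxidation list had a mean shift of 0.28, reached by 2 of 10 splits, with 0.33 in the highest other, too few splits for a share under 0.05. Hepatocyte markers had a median of -0.018, below the list's median by 0.227 with a standard error of 0.0648 over genes. With an array left out their median ran from -0.092 (without control replicate 1) to 0.017 (without control replicate 3). In the latter the gap was smallest, at 0.124 with a standard error of 0.0605. These errors leave out the spread between mice, and over arrays the markers' mean shift was -0.08 (95% interval -0.27 to 0.12). The gap therefore cannot decide on a higher share of hepatocytes. The part of the shift that goes with Dbp minus Arntl was 0.00162, with a 95% interval over arrays of -0.142 to 0.145 that ends short of the whole shift. That fit used 1 slope for both groups, but the list scores ran opposite ways. They were highest in control 1 (0.05) and in miR-143DOX 1 (0.33) within each group, the arrays at opposite clock extremes. The fit therefore cannot decide on the clock state as the whole cause. The shift itself had an interval that held 0 without the covariate (-0.11 to 0.67) and with it (0.28, -0.26 to 0.82). The clock, a higher share of hepatocytes, and an effect of the transgene, which was not tested, stay open.

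The unfolded protein response list had a mean shift of 0.21 in size, reached by 2 of 10 splits, with 0.22 in the highest other, too few for a share under 0.05. Without control replicate 3 its median was -0.090 against -0.19 with all arrays, so a large part of the median shift may come from high values in 1 control mouse. The part of the shift that goes with Dbp minus Arntl was -0.00419 (95% interval -0.115 to 0.106), short of the whole shift. That fit used 1 slope for both groups. Among miR-143DOX arrays the score was highest in replicate 3 (0.02), with the group's highest Dbp minus Arntl. Among control arrays it was highest in replicate 3 (0.28) and not in replicate 1 (0.03), which had that group's highest. The fit therefore cannot decide on the clock state as the whole cause. The shift itself had an interval that held 0 without the covariate (-0.52 to 0.09) and with it (-0.21, -0.62 to 0.21). The clock, and an effect of the transgene, which was not tested, stay open.

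The acute phase list had a mean shift of 0.18 in size, reached by 1 of 10 splits, with 0.12 in the highest other, too few for a share under 0.05. The clock state as the whole cause, taken as a straight line with 1 slope for both groups, is argued against. The part of the shift that goes with Dbp minus Arntl was 0.0073 (95% interval -0.0286 to 0.0432), and with that covariate the shift was -0.18 (-0.32 to -0.05). Among miR-143DOX arrays the score was highest in replicate 1 (-0.04), with the group's lowest Dbp minus Arntl. Among control arrays it was highest in replicate 3 (0.14), at neither end of that group's Dbp minus Arntl. The fit rests on 6 arrays, and a clock effect of another form stays open. A lower share of hepatocytes stays open, since the 24 hepatocyte markers outside the list had a median of -0.025, above the list's by 0.132 with a standard error of 0.077 (a gap of -0.132 as list minus markers). An effect of the transgene also stays open and was not tested.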
